A study of Mus musculus with 5 samples.

How the data were processed

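Gene expression was measured in whole mouse lung with 5 oligonucleotide arrays, 1 for each of 5 conditions, each hybridised with biotin-labelled RNA pooled from several animals per the labels. Groups were taken from the sample titles, and right ventricular pressures, the duration of hypoxia and ages from the titles and descriptions. The kind of error written after each pressure is not stated, nor is the number of animals in a pool.

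The deposited values were linear intensities, 1 per probe set. The table held 22626 probe sets and no control probe sets. The summary algorithm, background correction and scaling that the authors used are not given in the sources used here. In the table itself, no intensity lay under 50 and between 9.85% and 12.5% of the probe sets of each array sat at exactly 50, a lower limit already present in the deposited values. Column medians of the deposited intensities were 280 (BMPR2delx4+ with doxycycline), 270 (BMPR2delx4+ without doxycycline), 277 (hypoxia), 266 (wild type) and 284 (SM22-rtTA with doxycycline).

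From these values, log2 intensities were taken and each array was shifted so that all 5 shared a median over the 9047 probe sets above the 50th percentile of every array. The shifts were -0.04, -0.07, 0.08, 0.13 and -0.11 on the log2 scale, in the order of the medians above. A noise floor was set at the 50th percentile of the pooled shifted values, a scaled intensity of 276, and lower values were raised to it. Probe sets were named through the platform annotation, with symbols updated by gene ID from a RefSeq gene table on GRCm38.p6, which was used for names only. Of the probe sets, 20380 had 1 gene (20351 of them matched by gene ID), 691 had several and were not named, and 1555 had no gene listed. The probe set with the highest mean over the 5 arrays stood for its gene, which gave 12393 genes, 4956 of them with more than 1 probe set. Of these genes, 8590 were above the floor in at least 1 pool and are called measured below, and 5904 were above it in all pools. Per pool, 6820 to 7439 genes were above the floor. A ratio with a pool at the floor is a bound, written as "at least", and enters a list median at that bound.

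No replicate arrays exist, so no test was run and no p-value is given; the number of arrays limits the precision. The rules that follow, the gene lists, the named genes and the first set of alternatives were fixed before the data were examined. A gene was called higher where it was at least 1.5-fold above its matched control, above the floor, and above all 3 normal-pressure pools; lower was the mirror image. The matched control was the BMPR2delx4+ pool without doxycycline for the induced pool and the wild-type pool for the hypoxic pool. The 2 elevated-pressure pools were compared directly at 2-fold, among genes called in at least 1 comparison. For each of 40 gene lists (signalling pathways, cell types of the lung and of neighbouring tissues, stress and metabolism), the median log2 ratio over measured members was set against 10000 random lists of the same size matched on mean intensity in 20 bins, and its percentile among them describes these arrays only.

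Named genes were, for each main comparison, the 12 called genes with the highest and the 12 with the lowest ratio that were above the floor in both pools, without predicted loci; the 10 shared genes with the largest smaller ratio; the 10 with the largest direct difference; Bmpr2 and Tagln; and from each list up to 4 called members with the largest ratio, or the 2 with the highest mean where none was called. This gave 156 genes, of which 56 had more than 1 probe set; another probe set had the opposite sign for 2 of those called after induction and for 2 of those called in hypoxia. Other genes named below were chosen after their values were seen. Marker lists for proximal tubule, thick ascending limb and distal tubule, collecting duct, glomerulus, adrenal gland, liver and brown fat, 7 in all, were written after the data were examined.

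The calls were tested on simulated pools of the 12393 genes, with noise taken from the difference between the 2 transgenic normal-pressure pools and 200 genes changed in each elevated pool. In simulated induction, 86.0% of genes raised 2-fold, 80.0% of those lowered 2-fold, all of those raised 4-fold and 82.0% of those lowered 4-fold were recovered, and 514 of 12193 unchanged genes were called. In simulated hypoxia these values were 86.0%, 70.0%, 100% and 86.0%, with 586 unchanged genes called. The simulated wild-type pool had the noise of the transgenic pools, so these recoveries leave out the wider spread of the real wild-type pool. A further 100 sets of pools with no changed gene gave the counts that noise alone produces.

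Alternatives covered the scaling (as deposited, or quantile), the floor (30th or 70th percentile, or a pseudocount in place of the floor), the fold (2-fold), the gene summary (mean of probe sets, or each probe set by itself), the range of normal-pressure pools and the control. After the data were examined, the wild-type pool was left out, genes of other tissues were left out, and the correlation was computed with exchanged controls. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.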

Results

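Whole lungs were profiled from mice with raised right ventricular pressure of 2 origins. In SM22-tet-BMPR2delx4+ mice, doxycycline switches on a dominant-negative form of the bone morphogenetic protein (BMP) receptor BMPR2 in smooth muscle; the induced pool had a pressure of 50 ± 8 mmHg. The hypoxic pool came from FVB/N mice aged 8 weeks after 4 weeks of hypoxia, also at 50 ± 8 mmHg. Pools at 30 ± 3 mmHg were BMPR2delx4+ mice without doxycycline, wild-type FVB/N mice aged 8 weeks, and SM22-rtTA mice, which carry the doxycycline-dependent activator alone, on doxycycline. The titles of all 3 transgenic pools give 8 weeks, without saying whether this is age or treatment. Each condition was measured on 1 array of pooled RNA, so there are no replicates, and differences between pools are given as values without a test.

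The 3 normal-pressure pools were compared first, as the only measure of spread without raised pressure. Among the genes that set the wild-type pool apart were genes of the kidney. Miox, which starts myo-inositol breakdown, was at 10418 and the sodium-phosphate transporter Slc34a1 at 7945. Uromodulin (Umod) was at 7501 and kallikrein Klk1 at 9103, and all of these were at the noise floor in the other 4 pools. Of the measured proximal tubule markers, 22 of 24 were at least 2-fold higher in wild type than in any other pool, as were 6 of 10 thick ascending limb and distal tubule markers, 3 of 9 collecting duct markers and 0 of 3 glomerular markers. Steroidogenic Star was at 2165 and Cyp21a1 at 1883 there, with 6 of 13 adrenal markers at least 2-fold above the other pools, and albumin (Alb) was at 2894, with 4 of 14 liver markers so. Lung transcripts were high in the same pool, surfactant protein C (Sftpc) at 13368 and the club cell secretoglobin Scgb1a1 at 13194. All 30 measured oxidative phosphorylation genes were highest in wild type. The 2 transgenic pools differed at least 1.5-fold in 645 genes (258 higher and 387 lower with SM22-rtTA), with an SD of the log2 ratio of 0.34 over genes above the floor in all pools. Against wild type, SM22-rtTA differed in 2394 genes (880 higher, 1514 lower) and BMPR2delx4+ without doxycycline in 2588 (1124 higher, 1464 lower), with SDs of 0.62 and 0.63. These directions depend on the scaling: with values as deposited the splits were 1676 and 1022, and 1841 and 1017. With the listed genes of other tissues left out, at the main scaling, the splits were 875 and 1434, and 1117 and 1383. The listed markers thus make up few of the genes that differ from wild type.

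**Figure D1:**
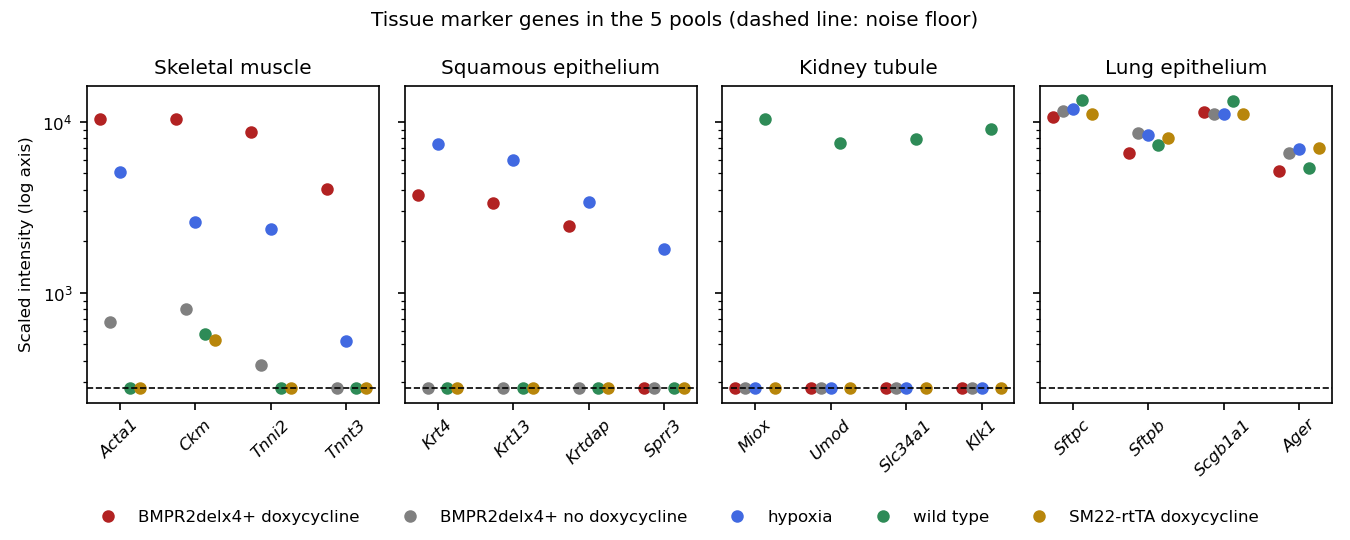
Scaled intensity on a log axis of 16 marker genes in the 5 pools, 1 point per array, with the noise floor of 276 as a dashed line. Skeletal muscle genes are highest in the induced pool (Acta1 10435), squamous genes in the hypoxic pool (Krt4 7459) and tubule genes in the wild-type pool (Miox 10418), while lung epithelial genes are high in all 5.

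Induction of BMPR2delx4+ was compared with the same genotype without doxycycline to find the genes that accompany the mutant receptor and raised pressure. Striated muscle genes were far higher in the induced pool. All 22 measured skeletal muscle genes were called higher, with a median log2 ratio of at least 3.24, the median intensity of the control being at the floor. Skeletal actin Acta1 was at 10435 against 677, muscle creatine kinase Ckm at 10428 against 799, fast troponin Tnni2 at 8770 against 379, and Tnnc2 at 6493 against the floor, at least 23.5-fold. Of 38 cardiac muscle genes 33 were higher, with a median of at least 1.58; many, such as myoglobin Mb at 7891 against 1052 and Myl3 at 5127 against 673, are also genes of slow skeletal muscle. The calcium pump Atp2a1 (4798 against 324), the muscle enolase Eno3 (4392 against 288), Sln, Myl1 and Pvalb moved with them. Keratins of stratified epithelium were higher as well, Krt4 at least 13.6-fold (3748) and Krt13 at least 12.1-fold (3333), with 8 of 14 oesophageal and upper airway genes called higher. Adipose genes were higher in 5 of 18 (9 of 18 without the wild-type pool), among them the thermogenic Ucp1 (1600, at least 5.79-fold) and Cidea (1582, at least 5.73-fold), and 6 of 8 brown fat markers, 7 of which stand in another list too, were higher. These bounds rest on the BMPR2delx4+ control, since Ucp1 was at 797 and Cidea at 1259 in wild type. The median intensity of brown fat markers was 1691 in the induced pool and 1367 in wild type, and that of adipose genes 1417 and 1431. Oxidative phosphorylation genes had a median of 0.60 with 0 of 30 called, and 29 of 30 above the control; all 30 were highest in wild type, and without that pool 16 of 30 were called higher.

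BMP-responsive genes had a median log2 ratio of -0.34 in the induced pool, with 6 of 11 measured members below 0 and 4 above. Id1, an inhibitor of differentiation and direct BMP target, was at 1576 against 2759, and between 2759 and 2837 in the 3 normal-pressure pools. Hey1 was at 781 against 1350 and the inhibitory Smad7 had a log2 ratio of -0.59. These 3 members were called lower and Id4 (525 against 325) higher; the list median was at percentile 0.04 of matched random lists, where other lists were as low, and was -0.32 against SM22-rtTA. Among BMP receptors, ligands and SMADs the co-receptor endoglin (Eng, 2651 against 4497) and Twsg1 (1048 against 1618) were the members called, of 21. Bmpr2 itself was at the floor in 4 pools and at 357 in SM22-rtTA; where its probe set lies relative to the transgene is not known, so it checks nothing about the induction. The medians of endothelial and alveolar markers were also under 0. The endothelial median was -0.37 (percentile 0, 29 of 33 members below 0), with Foxf1 (597 against 1161), Icam2 (2066 against 3734), Plvap and Eng called lower of 33, and the alveolar type 2 median was -0.39 (percentile 0, 20 of 22 below 0), with 5 of 22 called lower, including Napsa (1452 against 2936) and lysozyme Lyz2 (5464 against 8558), and 2 higher. Lyz2 is on the macrophage and monocyte list too, and Lcn2 and Chil1, also called lower, are on the neutrophil list. Alveolar type 1 markers had a median of -0.28 with 13 of 13 below 0 and 0 called. Neutrophil markers were at percentile 0 as well, heat shock genes at 0.01 and vasoactive genes at 0.02. Against SM22-rtTA the neutrophil median was -0.081 and the heat shock median 0.15. Macrophage and monocyte markers had a median of -0.17 (percentile 0.14, 3 of 19 called lower), and of -0.53 against SM22-rtTA. The vasoactive median was -0.17 against the matched control and -0.18 against SM22-rtTA. Fibroblast and club cell markers had medians of 0.00 and -0.03, and of -0.070 and 0.21 against SM22-rtTA.

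**Figure D2:**
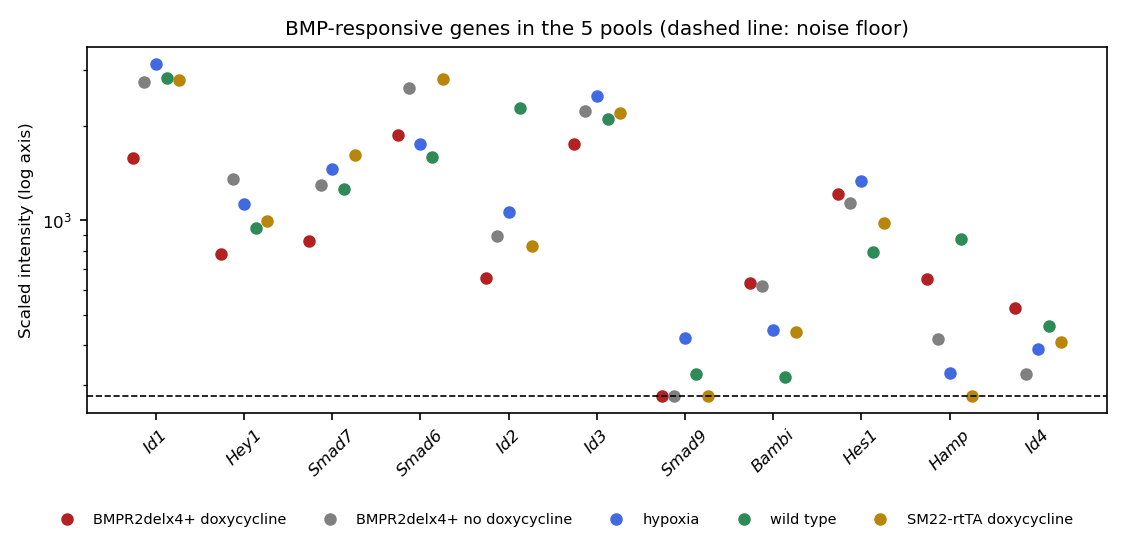
Scaled intensity on a log axis of the 11 measured BMP-responsive genes in the 5 pools, 1 point per array, ordered by the ratio of the induced pool to its control, with the noise floor as a dashed line. Id1 is at 1576 in the induced pool and between 2759 and 3153 in the others.

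Both subunits of soluble guanylate cyclase, the nitric oxide receptor, were lower in the induced pool, Gucy1a1 at 392 against 626 and Gucy1b1 at 1247 against 1989, as was the smooth muscle and pericyte integrin Itga8 (554 against 1392). The smooth muscle markers Tagln (3915 against 3633) and Acta2 (5655 against 5233) were not called. Against SM22-rtTA their log2 ratios were 0.50 and 0.80. Of 26 contractile genes 5 were higher, among them Tpm1 (6948 against 2241), Ldb3 and Pdlim3, which striated muscle also expresses. For Tpm1, 1 of 3 probe sets had the opposite sign. The 3 lower members were Itga8 and the guanylate cyclase subunits named above. The list median was 0.11 against the matched control and 0.41 against SM22-rtTA. In the matrix, the microfibril protein Mfap4 was at 1368 against 3968 and lumican (Lum) at 874 against the floor, with 34 of 36 genes not called. Basement membrane collagen Col4a3 (295 against 680), Col13a1 (424 against 1054), Igfbp3 (409 against 921) and the immunoglobulin heavy chain Igha (768 against 2178) were among the lowest ratios. Platelet genes were higher in 4 of 9 (Pf4 1.52-fold, Ppbp 1.51-fold, Itga2b 1.51-fold, Clec1b 1.74-fold), with a median of 0.47.

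In all, 280 genes were called higher and 113 lower in the induced pool, and 425 and 191 without the wild-type pool. For the first total, simulated pools with no changed gene gave 579 calls on average (522 to 629). The observed total is lower, but the simulated normal-pressure range leaves out the wider spread of the wild-type pool, so these counts are not alike. Of the called genes, 150 were at least 2-fold apart against 42.7 simulated (24 to 58), and 77 at least 3-fold against 0.24. Of the 150 genes, 129 were higher and 21 lower, and 76 of the 77 were higher. The simulated counts were not split by direction, so the lower calls of 2-fold or more were not set against noise by themselves. The noise was taken from the 2 transgenic normal-pressure pools, so it also holds their differences in genotype and doxycycline. Single calls under 2-fold, which include Id1, Hey1, Smad7, the guanylate cyclase subunits and the platelet genes, cannot be told apart from the noise of these arrays when taken by themselves.

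Hypoxia was compared with wild type to find the genes of raised pressure without the transgene. Squamous epithelial genes were highest in the hypoxic pool: Krt4 at 7459 and Krt13 at 5984, at least 27.0-fold and 21.7-fold above wild type, with Krtdap (3395), Sprr3 (1807) and the cornified envelope genes Lor (3917 against 618) and Lce3c (3688 against 332). For Lor the log2 ratio was -0.23 with the mean of its probe sets. Of the 14 measured genes of that list 8 were called higher and 1, Bpifa1, lower. Skeletal muscle genes were higher in 11 of 22, Acta1 at 5063 and at least 18.3-fold, Ckm at 2590 against 575. Other genes called higher were the chitinase-like Chil3 at 2806 against 1459, the protease inhibitor Slpi at 4364 against 1365, the interleukin-1 antagonist Il1rn at 1592 against 771 and Il18 at 835 against 435, with Fabp5 (4319 against 1272) and Aldh3a1 (1686 against 463). For Il1rn, 1 of 3 probe sets had the opposite sign. Chil3 was the 1 of 19 macrophage and monocyte markers called; their median was 0.29, and 0.02 without the wild-type pool. Of 28 immediate early and handling stress genes 7 were higher, with Junb (2482 against 1164) and Nr4a1 (4058 against 2340) among them; without the wild-type pool 4 were higher and 2 lower, and the median of 0.43 became 0.06. Targets of hypoxia-inducible factor gave 0 calls of 33, with Vegfa at 2186 against 1758 and Slc2a1 at 658 against 696, and a median of 0.02.

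The lower calls in hypoxia followed the wild-type pool. Oxidative phosphorylation genes had a median of -1.09, with 9 of 30 called (Ndufs1 575 against 2101, Sdha 1552 against 4202), and 0.04 against the mean of the transgenic controls. Adipose genes had a median of -1.02, and 0.15 against those controls. The lowest ratios were of genes much higher in wild type than in any other pool, such as Calml4 (307 against 3829, and 339 to 852 in the other 3 pools) and Dnajc12 (294 against 3226, and 393 to 462). Some genes were called lower both against wild type and against the mean of the transgenic controls. Igha was at 453 in the hypoxic pool and at 1478 or above in the 3 normal-pressure pools, and the immunoglobulin joining chain Jchain and Igfbp3 were at the floor, Igfbp3 at least 3.33-fold under wild type. The mitochondrial chaperonin Hspe1 (778 against 2638), the heat shock gene Hspa1b (2019 against 6567) and the airway secretory genes Bpifa1 (703 against 2555) and Bpifb1 (405 against 1176) were lower also. In SM22-rtTA these last genes were at 1164, 2618, 1008 and 547, in that order, nearer to the hypoxic values than wild type was. Heat shock genes had a median of -0.16 with 7 of 32 lower, a median that was 0.01 after quantile normalization.

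Alveolar and vessel lists were higher in the hypoxic pool relative to wild type and level with the transgenic controls. Alveolar type 2 markers had a median of 0.41 against wild type and 0.04 against the mean of the transgenic controls, alveolar type 1 markers 0.56 and 0.04, endothelial markers 0.27 and -0.03, smooth muscle contractile genes 0.42 and 0.00, and extracellular matrix genes 0.22 and 0.00. Pecam1 (3228 against 1308) and elastin Eln (2526 against 1402) were called against wild type and had log2 ratios of 0.32 and 0.28 against the transgenic controls. BMP-responsive genes had a median of 0.21 against wild type and 0.095 against the transgenic controls, with Id1 at 3153 against 2837. Hes1 was the member called, and without the wild-type pool it was not called, while Smad9 was higher and Smad6 lower.

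The hypoxic pool had 360 genes called higher and 414 lower, against 577 calls in simulated unchanged pools (508 to 639), and 285 of them at least 2-fold apart against 42.7 simulated (29 to 64). That noise was taken from the 2 transgenic pools and leaves out the wider spread of the wild-type pool, which was at least 2-fold apart from SM22-rtTA in 944 genes and from the BMPR2delx4+ control in 923. Of the 285 genes, 201 were lower. The split depends on the scaling, at 299 and 503 with values as deposited and 481 and 396 after quantile normalization. Calls under 2-fold, such as Il18 and Nr4a1, are by themselves within that noise; Chil3 was 1.92-fold above wild type and 4.22-fold above the transgenic controls. Without the wild-type pool, a control chosen after the data were examined, 1043 were higher and 357 lower, and 189 of the higher and 72 of the lower calls were kept.

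**Figure D3:**
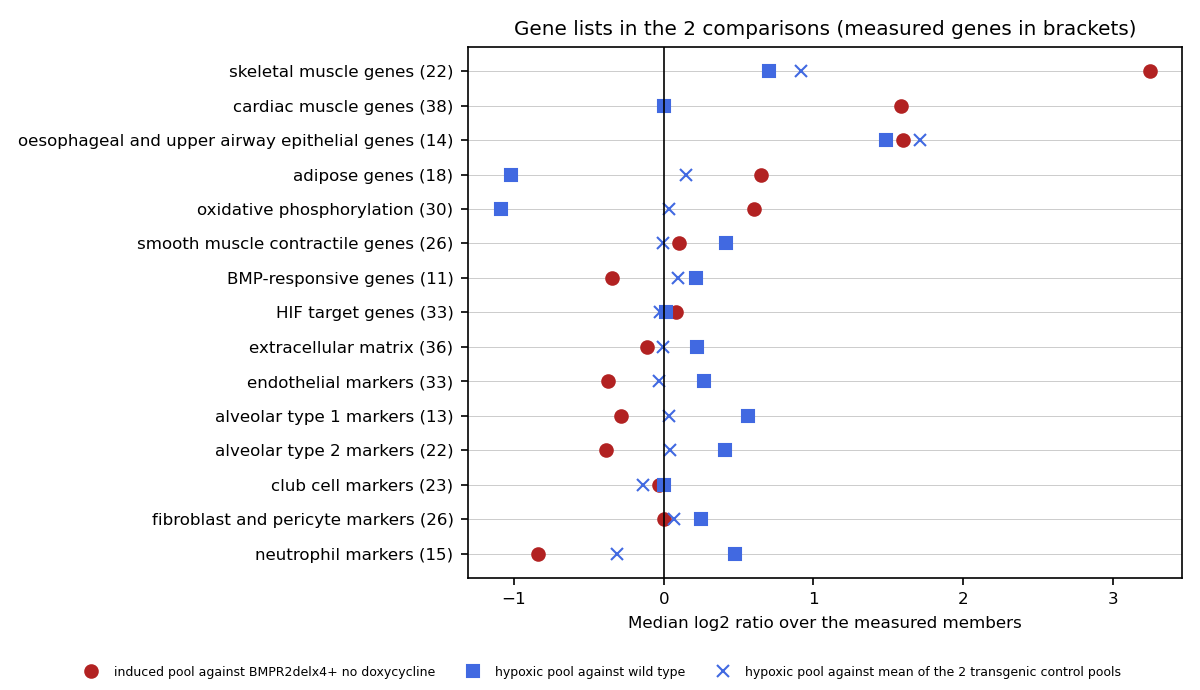
Median log2 ratio of 15 gene lists, with the number of measured genes in brackets, for the induced pool against its control (circles), the hypoxic pool against wild type (squares) and the hypoxic pool against the mean of the 2 transgenic control pools (crosses). Ratios with a pool at the floor enter at their bound. Skeletal muscle genes are at 3.24 or above in the induced pool, and oxidative phosphorylation genes are at -1.09 in hypoxia against wild type and at 0.04 against the transgenic controls.

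Muscle and squamous genes were among those shared by both forms of raised pressure. The 10 genes with the largest ratios in both were Krt4, Acta1, Krt13, Tnni2, Krtdap, Tnnc2, Ckm, Mt4, Myl1 and Mylpf, the last at 5278 and 1032 against the floor. Aldh3a1, Fabp5 and Xist were higher, and Igha and Igfbp3 lower, in both. Xist, expressed from the inactive X chromosome, was at the floor in wild type and SM22-rtTA. The share of female animals may therefore differ between the pools, which was not tested. In total 71 genes were called in the same direction, 62 higher and 9 lower, where independent lists would give 11.7 and 5.45 and simulated unchanged pools, which share the normal-pressure range, 35.9 (20 to 54). Without the wild-type pool 159 were, 118 higher and 41 lower, against 70.6 simulated (52 to 87). Part of the excess may thus come from the shared control pools, and 28 genes were called in opposite directions. By the matched ratio alone, with no array in common, 94 genes were apart in the same direction and 194 in opposite directions; with hypoxia set against SM22-rtTA, again with no array in common, these numbers were 164 and 17. Across the 8590 measured genes, which are not replicates, the 2 matched ratios had a Pearson correlation of -0.03 and a Spearman correlation of -0.09. With hypoxia set against SM22-rtTA these were 0.30 and 0.26, and with both controls exchanged 0.014 and -0.10, so the sign depends on the control. With the listed genes of other tissues left out, 8423 genes gave -0.11 and -0.10 for the matched ratios. With hypoxia set against SM22-rtTA these genes gave 0.25 and 0.26.

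The 2 elevated-pressure pools differed at least 2-fold in 226 called genes, 155 higher in the induced and 71 in the hypoxic pool. This split rests on the control of hypoxia: it was 201 and 198 without the wild-type pool, 209 and 186 with the mean of the 3 normal-pressure pools, and 142 and 163 with SM22-rtTA. It rests on genes of other tissues too, being 100 and 69 with the listed ones left out. Sarcomere genes led the first group, titin (Ttn) at 3093, myotilin (Myot) at 2417, Myh2 at 2190 and Ldb3 at 1869, all at the floor in hypoxia, and Actn2 at 2139 against 296. Lce3c (3688 against 349) and Chil3 (2806 against 318) led the second. BMP-responsive genes had a median of -0.51 in the induced relative to the hypoxic pool, Id1 at 1576 against 3153, beside -0.47 for alveolar type 2 and -0.23 for endothelial markers.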

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

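All tests of explanations in this part were chosen after the results were seen. Lists and genes are given here because the induced pool and the hypoxic pool moved in opposite directions relative to their matched controls; each arm is 1 array, and the difference was not tested. Neutrophil markers had a median log2 ratio of -0.84 after induction and 0.48 in hypoxia, their median intensity being at the noise floor in the induced and the wild-type pool, with S100a8 at 7119 in the BMPR2delx4+ control and at the floor in wild type. Against SM22-rtTA the induced median was -0.081, and without the wild-type pool the hypoxic median was -0.31, so the opposite directions rest on the matched controls. Col13a1 had -1.31 and 1.07, Lcn2, a secreted lipocalin at the floor in the induced pool, -1.70 or lower and 1.08, and the guanylate cyclase subunit Gucy1b1 -0.67 and 0.63. Against the mean of the transgenic controls the hypoxic values for these 3 genes were 0.13, 0.37 and 0.11.

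Adipose genes had 0.65 after induction and -1.02 in hypoxia, and oxidative phosphorylation genes 0.60 and -1.09. Both hypoxic values rest on the wild-type array, being 0.15 and 0.04 without it; that array was also high in brown fat markers, with a median intensity of 1367 against 282 in the BMPR2delx4+ control, and what set these values was not tested. The pattern weighed is that of kidney genes in the wild-type pool. An array holding kidney in place of lung is argued against by alveolar type 2 markers, 21 of 22 of which were above the floor there. A trait of FVB/N mice at this age is argued against by the hypoxic pool of the same strain and age, where 2 of 24 proximal tubule markers were within 2-fold of the wild-type level. Kidney tissue or RNA in the wild-type pool cannot be told apart from other sources: 28 of 34 tubule markers were at least 2-fold above every other pool, but these lists were written after the pattern was seen, and 3 of 9 collecting duct markers were.

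Alveolar type 2 markers had -0.39 after induction and 0.41 in hypoxia, and the first is set beside the BMP-responsive median of -0.34 in the induced pool. A smaller share of endothelial RNA cannot be told apart: the BMP-responsive median differed from the endothelial one by 0.027, but the alveolar type 2 median also lay within the quartiles of the endothelial members (-0.54 to -0.16). Dilution of all lung RNA alike by other tissue cannot be told apart either: the fibroblast median lay 0.38 above the endothelial one, while the quartiles of the 2 lists overlapped. Expression of BMPR2delx4+ predicts lower values against both transgenic controls, and the median was -0.32 against SM22-rtTA, where that of alveolar type 2 markers was -0.43. It stays open, since both ratios rest on the same induced array.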

How the results depend on the processing

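No paired analysis was possible because each group has 1 sample. Leaving out the wild-type pool, leaving out genes of other tissues and exchanging the controls were chosen after the data were examined, as were the gene lists recomputed beyond the 17 planned ones; all other alternatives were planned. Of 106 counts and correlations under an alternative, 61 stayed within 1.5 times the main count (or 0.05 of the main correlation) and 45 moved further; of 600 medians of the 40 lists, 487 moved by less than the SD across the 3 normal-pressure pools, 101 moved further and 12 changed sign, counted where the main median lay in the outer 5% of random lists; of 1298 ratios of called named genes the numbers were 885, 412 and 1. These ratios do not involve the fold threshold. Counts are given below as higher and lower, after induction and then in hypoxia, and normal-pressure pairs as SM22-rtTA with wild type, BMPR2delx4+ control with wild type, and SM22-rtTA with BMPR2delx4+ control. With the floor at the 70th percentile, fewer genes could be called by construction: 171 and 69, 181 and 252, with 32 shared, 137 between the elevated-pressure pools, and 1360, 1455 and 310 between normal-pressure pools. With the floor at the 30th percentile, 584 genes were higher in hypoxia, 119 were shared, 380 differed between the elevated-pressure pools and 1002 in the last normal-pressure pair. A 2-fold threshold, stricter by construction, gave 129 and 21, 84 and 201, with 30 shared and 944, 923 and 106 between normal-pressure pools. Counting each probe set by itself gave 433 and 221 after induction, 677 lower in hypoxia, 391 between the elevated-pressure pools, and 3999, 4034 and 1455 between normal-pressure pools. The matched ratio alone, a looser rule by construction, gave 433 and 221, 652 and 1021; the counts after induction equal those by probe set, although the 433 higher probe sets stand for 331 named genes, 285 of which are among the 433 genes. With the mean of the 3 normal-pressure pools as control, the counts were 449 and 201, 638 and 273, the neutrophil median in hypoxia was -0.12, and the medians after induction were -0.11 for B cell and 0.11 for glucocorticoid-responsive genes. The correlation was then 0.25, but both ratios share their denominator, which by construction favours a positive value. With SM22-rtTA as control of the induced pool, they were 576 and 311. Without the wild-type pool, 425 and 191 were called after induction, 1043 were higher in hypoxia, 159 were shared and 399 differed between the elevated-pressure pools; hypoxic medians changed sign for smooth muscle contractile genes (-0.0023), extracellular matrix (-0.0043), endothelial markers (-0.030), neutrophil markers (-0.31), mesothelial markers (-0.036), adipose genes (0.15), oxidative phosphorylation (0.036) and xenobiotic enzymes (0.013). Medians nearer to those of random lists changed sign too, among them platelet (0.30 to -0.33), B cell (0.13 to -0.41) and BMP receptor and SMAD genes (0.20 to -0.16). With hypoxia against SM22-rtTA, the correlation was 0.30. After quantile normalization the heat shock median in hypoxia was 0.0094, and with the mean of all probe sets Lor in hypoxia was -0.23. The cause was not tested except where the construction is named. Signal over background limits the lower calls, since a gene near the floor can show no further decrease. Values as deposited moved the median ratio of the SM22-rtTA to the wild-type pool by 0.22 on the log2 scale, and of the BMPR2delx4+ control to the wild-type pool by 0.18.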

Other observations

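The SM22-rtTA pool differed from the others in single genes chosen after their values were seen. Cd79a, a part of the B cell receptor, was at 1792 there and at 478 or less in the other pools, and Ms4a1 (CD20) at 1277 against 495 or less. The glucocorticoid-responsive genes Fkbp5 and Zbtb16 were at 279 and 700 there, and at 667 and 1827 or above elsewhere, and the clock output gene Dbp was at 373 against 791 or above. The list of glucocorticoid-responsive genes had a median log2 ratio of -0.02 in SM22-rtTA against wild type and -0.51 against the BMPR2delx4+ control, and its member Sgk1 was highest in SM22-rtTA (3331). Thymocyte genes were higher in the induced pool, with 4 of 5 called: Rag1 (788, at least 2.85-fold), Satb1 (1234 against 371), Ccr9 and Dntt. The bound for Rag1 rests on the BMPR2delx4+ control, since Rag1 was at 628 in wild type, 534 in hypoxia and 409 in SM22-rtTA. Xist, expressed from the inactive X chromosome, was at 1845 in the induced, 1403 in the hypoxic and 689 in the BMPR2delx4+ control pool. It was at the floor in wild type and SM22-rtTA. Of the 3 measured genes of the sex-linked list, the 2 besides Xist were highest in wild type, 1 of them being at the floor in the other 4 pools. Whether the pools differ in the sex of their animals was not tested.

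The muscle and squamous genes of the elevated-pressure pools were weighed with tests chosen after the values were seen. A response set by the recorded pressure is argued against by the skeletal muscle genes, 1 of 22 of which was within 2-fold between the induced and the hypoxic pool at the same recorded pressure. For the squamous genes it stays open, with 11 of 14 within 2-fold. A single neighbouring tissue of fixed make-up in both pools is argued against by the log2 ratios of the induced to the hypoxic pool, whose medians for skeletal muscle and squamous genes lay 2.61 apart, with quartiles from 1.84 to 2.72 and from -0.84 to 0.00. These ratios cover only a fixed make-up. Neighbouring tissue whose make-up differed between the pools was not weighed and stays open. Muscle tissue in the induced pool cannot be told apart from an effect of the transgene in lung: 55 of 60 cardiac and skeletal muscle genes were called higher there, which restates the pattern, and in the hypoxic pool, which has no transgene, 11 of 22 skeletal and 5 of 38 cardiac genes were.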
